A study of Homo sapiens with 15 samples.

How the data were processed

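Total RNA of ZR-75-1 cells, a human breast cancer line, was amplified, labelled with biotin and measured on 15 Affymetrix arrays, per the labels' protocols. Per the labels, the cells received 10 nM MPA, PROG, DHT or DEX, or 0.1% ethanol as vehicle, for 6 h, and each of the 5 groups has 3 arrays. The sample titles also call the vehicle arrays untreated, and the solvent of the treated cells is not given in the sources used here. Group and replicate number were taken from the sample titles. The full names of the 4 compounds are the usual reading of these abbreviations, which the labels do not spell out.

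The deposited table holds log2 expression values of 34878 probe sets with 2 decimals, 1 column per array. Partek and RMA are named in the submitters' processing notes. Their versions and settings, the background correction, any filter and the genome build are not given in the sources used here. RMA sets the arrays to a like distribution and summarises probes on the log2 scale, and the deposited medians of 3.69 to 3.73 per array show like distributions. RMA can compress changes of dim probe sets, and a change common to most genes would be removed by such a normalization. The platform annotation pairs 14841 probe sets with 1 gene symbol, 0 with several, and leaves 20037 unnamed here. The symbols were updated through a RefSeq gene table, which was used for names and for which genes neighbour each other, and no coordinates are given. Of the 14361 genes, 405 have more than 1 probe set. The named probe sets include 12226 of protein-coding genes, 1365 of long non-coding RNAs and 732 of microRNA genes.

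Values were used as deposited, with no further normalization and no filter on dim probe sets. For each of the 14841 named probe sets limma 3.58.1 in R 4.3.3 (lmFit and eBayes) fitted 5 group means over all 15 arrays, with 10 residual degrees of freedom and a prior of 3.81. The 4 compounds were compared with vehicle and with each other in 10 contrasts, 2-sided, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. A moderated F test over the 4 contrasts against vehicle summarised any difference among the groups. Every adjusted p of a gene comes from these limma fits, and intervals are 95% intervals of the same fits.

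The 27 gene lists were tested with limma's camera at a preset correlation of 0.01, on the probe set with the highest mean of each gene, with Benjamini-Hochberg adjustment over 108 tests against vehicle and 162 between compounds. They hold androgen-induced, glucocorticoid-induced, progestin-induced and estrogen-induced genes, androgen-regulated secreted proteins, steroid metabolism enzymes, steroid receptors and co-regulators, circadian clock genes, metallothioneins, immediate early genes, NF-kB inflammatory genes, interferon-induced genes, sterol synthesis genes, fatty acid genes, G1-S genes, mitotic genes, unfolded protein response genes, heat shock genes, hypoxia genes, sodium and water transport genes, polyamine enzymes, luminal, basal, fibroblast and blood or endothelial markers, ribosomal protein genes and housekeeping genes. Camera was repeated with a correlation estimated from the data, which kept 21 of 34 calls against vehicle and 20 of 43 between compounds, and fry was run as another alternative. Where a call in the text holds with the estimated correlation, only the preset value is given, and between compounds the text gives only the androgen, glucocorticoid, progestin and some metallothionein results. Preset values can be far smaller. For a simulated list raised by 0.2 with MPA, the camera adjusted p was 6.71e-38 with the preset and 1.89e-05 with the estimated correlation. The size of a preset value is therefore no measure of the strength of evidence. Only list members with a named probe set were tested, for example 22 of 42 androgen-induced genes and 6 of 18 sodium and water transport genes. Numbers of called members are given over all genes tested and adjusted over the list alone. In 57 of the 270 list tests the median, mean and test differed in sign, and 2 of those were called, both for steroid receptors and co-regulators.

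Genes named in the text follow a rule. Against vehicle these are the 10 largest called changes in each direction whose 3 treated arrays all lie on 1 side of the 3 vehicle arrays, up to 4 called members of each list with a camera call or at least 2 called members, and PGR, NR3C1, ESR1, FKBP5, ZBTB16, TSC22D3, PER1, SGK1, KLF9, PIP and KLK3. A further gene of the rule is not reported here. Between compounds these are the 5 largest in each direction by the same rule and the same single genes. The text gives part of them, mostly those whose calls held with each array left out, a choice made after the values were seen. Named outside the rule, after their values were seen, are OLR1 against vehicle, KLHDC10, the neighbours of ESR1 and the genes highest in DHT 1 and DHT 2. An earlier run of the code took up to 6 members of each list and lists between compounds, and it was set back to the fixed rule. Counts of list members and shared calls with 1 array left out were tabulated after the main results were seen. Pseudogenes, small RNAs and duplicated copies are passed over. The groups, the tests of the comparisons, the lists, this rule and the alternatives were chosen before the data were examined. The tests of patterns in the closing part were chosen after the data had been examined, and those on the probe sets highest in DHT 1 and DHT 2 after that result was seen. For the genes higher with DHT than with DEX, the reading of the matched draws was narrowed after their values were seen: the bound set before was a share under 0.05, and a median outside the 95% range of the draws was then required as well, which leaves both explanations open.

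Responses were compared by shared calls, correlation and covariance across genes, beside 100 simulations of unchanged groups against the shared vehicle arrays and beside the overlap of independent lists. The alternatives were the replicate number as a block, a filter at the 40th percentile of the mean level (log2 3.9), all probe sets of the table, the mean of a gene's probe sets, quantile normalization, median centring, eBayes with trend and robust settings, no moderation, array weights, only the 2 groups compared, a minimum of 1.5-fold and leaving out each array in turn. Other splits of the arrays were fitted as well. The steps were tested on simulated data of MPA against vehicle with 14841 probe sets, 200 of them changed. Of changes of 0.3 on the log2 scale 61.2% were recovered, of 0.5 94.0% and of 1 all 66, with 11 false among 181 calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.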

Results

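ZR-75-1, an estrogen receptor-positive human breast cancer cell line, was exposed for 6 h to 10 nM of 1 of 4 steroid compounds or to vehicle, 0.1% ethanol, and total RNA was measured on 15 Affymetrix expression arrays. MPA is medroxyprogesterone acetate, a synthetic progestin that carries the progesterone skeleton with an added methyl and an acetoxy group. PROG is progesterone, DHT is dihydrotestosterone, a potent androgen, and DEX is dexamethasone, a fluorinated and methylated synthetic glucocorticoid. Each of the 5 groups had 3 arrays, so their number limits the precision of every value. The deposited log2 levels had a median of 3.69 to 3.73 on each array, and arrays of 1 group correlated with r = 0.997 to 0.998 across all probe sets. The tests used the 14841 probe sets paired here with 1 gene symbol, which cover 14361 genes. Changes are log2 differences, first group minus second, ± the standard error of limma's fit, with n = 3 arrays per group, and a probe set is called at a limma adjusted p under 0.05. The treatment protocol gives the controls 0.1% ethanol while their sample labels also call them untreated, and no label gives the solvent of the compounds, so a solvent effect common to the treated groups may be part of each comparison with vehicle, but not of differences between compounds. The labels do not say that the arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The receptor gene NR3C1 and the glucocorticoid-response gene TSC22D3 have no named probe set here and were not analysed here.

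The first question, from the design, was what MPA did relative to vehicle. RANBP3L, a RAN-binding protein family member, rose at least 5.13-fold (log2 change 2.36 ± 0.097, adjusted p = 1.75e-09), a lower bound because its vehicle mean of 3.53 lies under the array medians. C1orf116, known as specifically androgen-regulated gene protein, rose 5.09-fold (2.35 ± 0.056, adjusted p = 8.29e-12). FKBP5, a co-chaperone of steroid receptors, rose by 2.16 ± 0.13, adjusted p = 8.79e-08, and PER1, a circadian clock repressor, by 1.88 ± 0.10, adjusted p = 2.86e-08. CLDN8, a tight junction claudin, rose by 2.02 ± 0.085, the zinc finger gene ZBTB7C by 2.28 ± 0.12, and HSD11B2, the enzyme that inactivates cortisol, by 1.70 ± 0.065. Among the genes that fell were AMIGO2, a cell adhesion protein (-1.23 ± 0.10, adjusted p = 1.81e-06), HEY2, a Notch-responsive repressor (-1.01 ± 0.089), and the chemokine receptor CXCR4 (-0.77 ± 0.12). The receptor genes ESR1, for estrogen receptor alpha, and PGR, for the progesterone receptor, fell to 0.588 and 0.643 of the vehicle level (-0.77 ± 0.065, adjusted p = 2.10e-06, and -0.64 ± 0.056, adjusted p = 3.35e-06). BCL2, an inhibitor of apoptosis, fell by a log2 change of -0.68 ± 0.039, adjusted p = 4.35e-08. In all, 880 probe sets were called, 610 higher and 270 lower, and 168 of them differed by at least 1.5-fold. PIP was not called (0.22 ± 0.067, adjusted p = 0.0799). SGK1, a glucocorticoid-responsive kinase, ZBTB16 and KLK3 had means under the array medians in all 5 groups, so neither a difference nor its absence can be read for them with any compound. For SGK1 the values were 0.27 ± 0.064, adjusted p = 0.0210 with MPA, a call that ended without any 1 of vehicle 1, MPA 2 and MPA 3 (adjusted p 0.0568 to 0.0939), and 0.38 ± 0.064, adjusted p = 0.00294 with PROG.

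Of the gene groups, 19 of 29 measured glucocorticoid-induced genes rose with MPA and 1 fell, or 23 higher and 1 lower when adjusted over the list alone. Examples are the acyl-CoA synthetase gene ACSL1 (1.54 ± 0.050) and the zinc finger transcription factor gene KLF9 (1.47 ± 0.092). The list stood above the other genes in limma's camera test (adjusted p = 1.30e-28). Progestin-induced genes rose in 17 of 27 cases and fell in 2, or 20 higher and 2 lower when adjusted over the list alone, among them THBS1, a matricellular protein (1.29 ± 0.053; camera adjusted p = 1.74e-21). Of the androgen-induced genes, 9 of 22 rose and 0 fell, or 10 higher and 0 lower when adjusted over the list alone, with the stress-response gene NDRG1 (1.48 ± 0.17) beside C1orf116, FKBP5 and CLDN8 (camera adjusted p = 2.00e-11). The glucocorticoid and progestin lists share 8 measured members, the androgen and glucocorticoid lists 3 and the androgen and progestin lists 2, so their counts are not independent. Other lists share members with the glucocorticoid list as well. These are MT1X and MT2A of the metallothioneins, DUSP1 of the immediate early genes, ACSL1 of the fatty acid genes, PER1 of the clock genes and FKBP5 of the receptor list. Immediate early genes, which respond to stimuli without new protein synthesis, rose in 6 of 17 cases, or 12 higher and 0 lower when adjusted over the list alone (camera adjusted p = 3.94e-12). The transcription factor genes JUN (0.92 ± 0.074) and FOSL2 (0.74 ± 0.046) are examples. The metal-binding metallothioneins MT2A (0.70 ± 0.046) and MT1F (0.33 ± 0.056) rose among 8 measured, or 4 higher and 0 lower when adjusted over the list alone (camera adjusted p = 6.21e-04). Fatty acid synthesis and storage genes rose in 8 of 19 cases and fell in 1, or 8 higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.55e-05). They include THRSP, a regulator of lipogenesis (1.03 ± 0.19), and the desaturase FADS1 (0.46 ± 0.066). Of 10 steroid receptors and co-regulators, ESR1, PGR and the pioneer factor FOXA1 (-0.31 ± 0.047) fell and FKBP5 rose, or 1 higher and 4 lower when adjusted over the list alone. Camera placed that list lower (adjusted p = 0.0240; adjusted p = 0.0798 with an estimated correlation), with a median change of -0.078 but a mean of 0.02, and the call ended without vehicle 2 (adjusted p = 0.0595). Of 25 estrogen-induced genes 6 rose, including the estrogen-response gene GREB1 (0.86 ± 0.047), and 2 fell, or 7 higher and 3 lower when adjusted over the list alone, without a camera call (adjusted p = 0.0637). Leaving out 1 array took the 8 raised fatty acid genes to 5 without vehicle 1, vehicle 2, MPA 2 or MPA 3, and the 2 lowered progestin-induced genes to 1 without vehicle 1, vehicle 3 or MPA 2 and 0 without vehicle 2 or MPA 1.

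**Figure D1:**
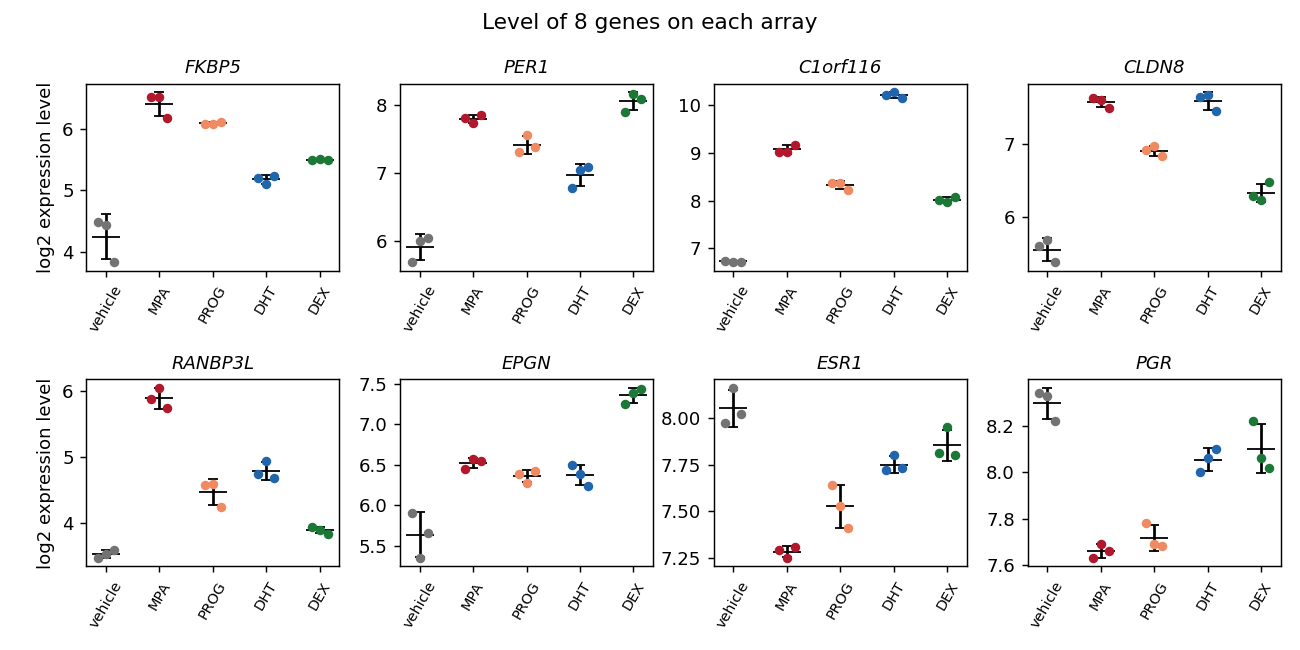
Each panel plots the log2 expression level (vertical axis) of 1 gene in the 5 groups (horizontal axis), with a point for each array, a dash for the mean and bars of ± 1 SD over 3 arrays. FKBP5 and PER1 lie above vehicle with all 4 compounds, C1orf116 is highest with DHT at a change of 3.48, and EPGN is highest with DEX. ESR1 is lowest with MPA, and PGR is lowest with MPA and PROG, whose arrays overlap. Each panel has its own vertical scale, which does not start at 0.

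PROG against vehicle raised ZBTB7C by 2.06 ± 0.12, adjusted p = 1.28e-07, FKBP5 by 1.85 ± 0.13, adjusted p = 8.50e-07 and EMP1, an epithelial membrane protein, by 1.85 ± 0.089, adjusted p = 1.89e-08. C1orf116 rose 3.02-fold (1.59 ± 0.056), PER1 2.83-fold, and the acyl-CoA thioesterase family gene ACOT6 2.65-fold (1.41 ± 0.12). HEY2 (-0.69 ± 0.089, adjusted p = 2.87e-04), AMIGO2 (-0.68 ± 0.10, adjusted p = 0.00126), PGR (-0.58 ± 0.056, adjusted p = 1.71e-05) and ESR1 (-0.52 ± 0.065, adjusted p = 1.80e-04) fell. CCDC170 (-0.55 ± 0.065) and RMND1 (-0.41 ± 0.059), the nearest measured protein-coding genes on 1 side of ESR1, and BCL2 (-0.42 ± 0.039) fell as well. The calls numbered 419, 361 higher and 58 lower, and 85 were of at least 1.5-fold. Glucocorticoid-induced genes rose in 17 of 29 cases and fell in 1, or 19 higher and 1 lower when adjusted over the list alone, with KLF9 (1.25 ± 0.092) and ACSL1 (1.18 ± 0.050) as examples (camera adjusted p = 1.30e-28). Progestin-induced genes rose in 14 of 27 cases, or 17 higher and 2 lower when adjusted over the list alone, including HSD11B2 (1.32 ± 0.065) and THBS1 (1.05 ± 0.053; camera adjusted p = 6.85e-21). Androgen-induced genes rose in 8 of 22 cases, or 9 higher and 0 lower when adjusted over the list alone, with CLDN8 (1.35 ± 0.085) and NDRG1 (1.28 ± 0.17) among them (camera adjusted p = 2.44e-08). Immediate early genes rose in 4 of 17 cases, or 11 higher and 0 lower when adjusted over the list alone, with JUN at 0.67 ± 0.074 and FOSL2 at 0.66 ± 0.046 (camera adjusted p = 1.74e-10). Of the 8 metallothioneins 2 rose, or 2 higher and 0 lower when adjusted over the list alone, with MT2A at 0.55 ± 0.046 (camera adjusted p = 0.00316). Fatty acid genes rose in 2 of 19 cases, or 4 higher and 0 lower when adjusted over the list alone, ACSL1 and the elongase ELOVL5 (0.32 ± 0.050; camera adjusted p = 6.57e-04, adjusted p = 0.0798 with an estimated correlation). Of the steroid receptors and co-regulators 2 fell and 1 rose, or 1 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.0292; adjusted p = 0.0817 with an estimated correlation; median -0.067, mean 0.037). Of the estrogen-induced genes 4 rose and 1 fell, or 7 higher and 2 lower when adjusted over the list alone, with no camera call (adjusted p = 0.0942). Without PROG 2 the number of calls was 257, and the receptor list lost its call without vehicle 2 (adjusted p = 0.0770), vehicle 3 (adjusted p = 0.0539) or PROG 2 (adjusted p = 0.0808). The number of raised estrogen-induced genes became 2 without vehicle 1, vehicle 2, PROG 1 or PROG 2, of metallothioneins 1 without any 1 of the 6 arrays, and of lowered glucocorticoid-induced genes 0 without vehicle 1, vehicle 2, vehicle 3, PROG 1 or PROG 2.

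DHT against vehicle raised C1orf116 11.2-fold (3.48 ± 0.056, adjusted p = 3.70e-14) and CLDN8 4.07-fold (2.03 ± 0.085, adjusted p = 1.00e-08). RANBP3L rose from its dim vehicle level by at least 1.26 ± 0.097, adjusted p = 1.17e-05, AQP3, a water and glycerol channel, by 1.11 ± 0.11, adjusted p = 1.07e-04, and PER1 by 1.06 ± 0.10, adjusted p = 1.07e-04. EAF2, an ELL-associated elongation factor (0.95 ± 0.062), KDM4B, a histone demethylase (0.76 ± 0.11), and FKBP5 (0.93 ± 0.13, adjusted p = 0.00299) also rose. BCL2 (-0.35 ± 0.039, adjusted p = 2.60e-04) and SOSTDC1, a secreted BMP and WNT antagonist (-0.47 ± 0.073, adjusted p = 0.00546), fell. The calls numbered 132, 115 higher and 17 lower, and 25 were of at least 1.5-fold. Androgen-induced genes rose in 5 of 22 cases, or 8 higher and 0 lower when adjusted over the list alone, with IQGAP2, a scaffold protein (0.41 ± 0.061), as a further example (camera adjusted p = 1.74e-10). Progestin-induced genes rose in 5 of 27 cases, or 5 higher and 0 lower when adjusted over the list alone, including HSD11B2 (0.64 ± 0.065) and THBS1 (0.48 ± 0.053; camera adjusted p = 1.61e-04). Of the glucocorticoid-induced genes 5 of 29 rose, or 7 higher and 2 lower when adjusted over the list alone (camera adjusted p = 3.87e-04; adjusted p = 0.0551 with an estimated correlation). Among them were KLF9 (0.63 ± 0.092) and BCL6, a transcriptional repressor (0.53 ± 0.053). No immediate early gene was called over all genes, 2 higher and 0 lower when adjusted over the list alone (camera adjusted p = 0.00316; adjusted p = 0.160 with an estimated correlation). No metallothionein was called, with 1 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.931). The fatty acid list had 1 call, or 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0538). For the receptor list it was 1 higher and 1 lower, or 2 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.931), and for the estrogen list 2 higher, or 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.103). Of the 10 largest falls with DHT by the naming rule, which passes over small RNAs and pseudogenes, 7 lost their calls when 1 array was left out. The largest of these, CXCR4 (-0.54 ± 0.12, adjusted p = 0.0486), lost it without any 1 of vehicle 1, vehicle 2, vehicle 3, DHT 1 and DHT 2 (adjusted p 0.110 to 0.197). The ESR1 difference of -0.30 ± 0.065, adjusted p = 0.0486 lost its call without any 1 of the 6 arrays (adjusted p 0.0517 to 0.175), and PGR was not called (-0.24 ± 0.056, adjusted p = 0.0634). The number of calls fell to 79 without vehicle 2, 79 without DHT 1 and 66 without DHT 2. The 25 of at least 1.5-fold became 16 without vehicle 2, 15 without DHT 2 and 45 without DHT 3. The number of raised estrogen-induced genes became 1 without vehicle 1, vehicle 2 or DHT 1, of fatty acid genes 0 without vehicle 1, vehicle 2, vehicle 3, DHT 2 or DHT 3, and of lowered receptor genes 0 without any 1 of the 6 arrays. In addition 16 probe sets were highest by over 0.3 in DHT 1 and DHT 2 alone, and 3 of these are among the calls.

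DEX against vehicle raised PER1 4.41-fold (2.14 ± 0.10, adjusted p = 7.54e-08) and EPGN, an epidermal growth factor family ligand, 3.29-fold (1.72 ± 0.11, adjusted p = 1.05e-06). C1orf116 rose by 1.30 ± 0.056, adjusted p = 2.67e-08, and FKBP5 by 1.26 ± 0.13, adjusted p = 1.81e-04. KLF9 rose by 1.10 ± 0.092, BCL6 by 1.01 ± 0.053 and ANGPTL4, a secreted inhibitor of lipoprotein lipase, by 0.92 ± 0.082, adjusted p = 4.01e-05. The long non-coding RNA TSPEAR-AS2 (-0.43 ± 0.051, adjusted p = 4.05e-04, to a DEX mean of 3.65, under the array medians) and the DNA-binding protein gene ARID3B (-0.28 ± 0.044, adjusted p = 0.00544) fell. Of the 10 largest falls with DEX by the same rule 8 lost their calls when 1 array was left out. The largest of these, AMIGO2 (-0.53 ± 0.10, adjusted p = 0.0224), lost it without any 1 of vehicle 1, vehicle 2, DEX 1 and DEX 2 (adjusted p 0.0787 to 0.106). ESR1 (-0.20 ± 0.065, adjusted p = 0.248), PGR (-0.20 ± 0.056, adjusted p = 0.164) and PIP (0.30 ± 0.067, adjusted p = 0.0529) were not called. The calls numbered 164, 142 higher and 22 lower, and 21 were of at least 1.5-fold. Glucocorticoid-induced genes rose in 11 of 29 cases, or 16 higher and 0 lower when adjusted over the list alone, including IRS2 (0.68 ± 0.071) and DUSP1, a MAP kinase phosphatase (0.51 ± 0.060; camera adjusted p = 2.91e-19). Progestin-induced genes rose in 9 of 27 cases, or 12 higher and 1 lower when adjusted over the list alone, with HSD11B2 at 0.93 ± 0.065 (camera adjusted p = 6.99e-10). Of the androgen-induced genes 3 of 22 rose, C1orf116, FKBP5 and CLDN8 (0.78 ± 0.085), or 5 higher and 0 lower when adjusted over the list alone (camera adjusted p = 1.67e-04; adjusted p = 0.0798 with an estimated correlation). Immediate early genes rose in 5 of 17 cases, or 8 higher and 0 lower when adjusted over the list alone, with FOSL2 at 0.40 ± 0.046 (camera adjusted p = 9.17e-06). MT2A (0.30 ± 0.046) was the 1 metallothionein called, or 3 higher and 0 lower when adjusted over the list alone (camera adjusted p = 2.26e-04). In the fatty acid list no member was called, 1 higher and 0 lower when adjusted over the list alone. Camera still placed it higher (adjusted p = 0.0240; adjusted p = 0.231 with an estimated correlation), a call lost without vehicle 3 (adjusted p = 0.0559), DEX 2 (adjusted p = 0.0665) or DEX 3 (adjusted p = 0.119). The receptor list had 1 call, FKBP5, or 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.523). In the estrogen list the numbers were 2 higher and 1 lower, or 6 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0761). Leaving out 1 array took the number of calls to 87 without vehicle 1, 104 without vehicle 2, 99 without vehicle 3, 95 without DEX 2 and 78 without DEX 3. The 9 raised progestin-induced genes became 5 without vehicle 1, DEX 2 or DEX 3, the 5 immediate early genes 3 without vehicle 1, vehicle 2, vehicle 3, DEX 2 or DEX 3, and the metallothioneins 2 without vehicle 2. The raised estrogen-induced genes became 1 without vehicle 1, vehicle 2, DEX 2 or DEX 3, the lowered one 0 without vehicle 1, vehicle 3 or DEX 3, and the 0 lowered receptor genes 1 without DEX 1.

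**Figure D2:**
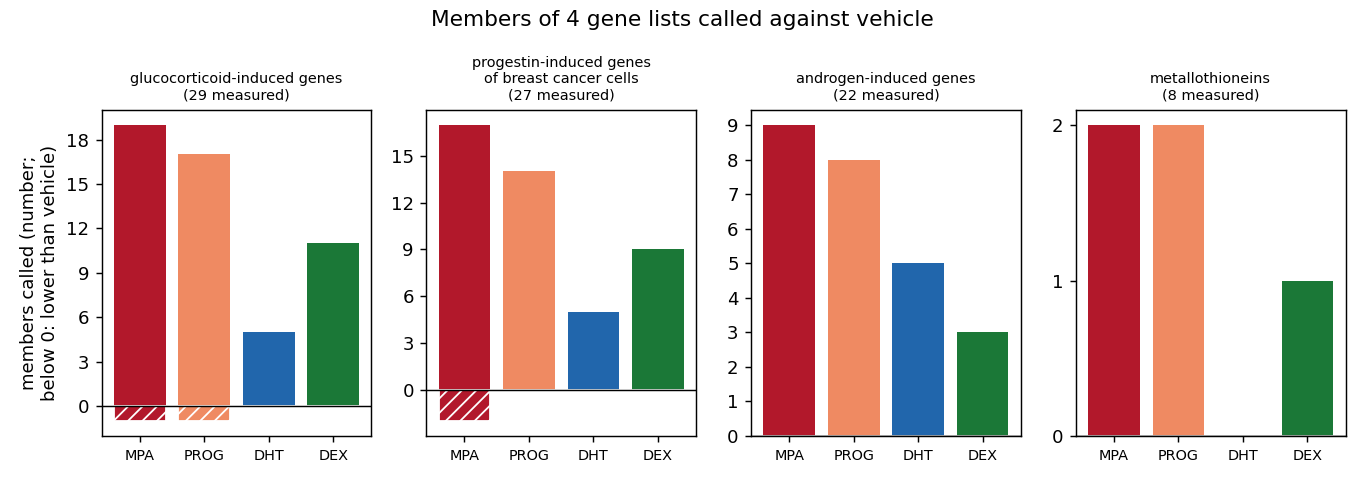
Bars give the number of members (vertical axis, starting at 0) of 4 gene lists called higher than vehicle with each compound (horizontal axis), and hatched bars below 0 those called lower, out of the number measured in each title. The glucocorticoid-induced list has 19 higher members with MPA, 17 with PROG, 5 with DHT and 11 with DEX, and the androgen-induced list 9, 8, 5 and 3.

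MPA and PROG, which differ by the added methyl and acetoxy groups, were compared at the same dose and time. RANBP3L was higher with MPA by 1.42 ± 0.097, adjusted p = 1.25e-05 (95% interval 1.21 to 1.62). ATP13A4, a P-type ATPase, was higher by 0.93 ± 0.091, adjusted p = 2.55e-04, UNC5B, a netrin receptor, by 0.83 ± 0.080, adjusted p = 2.55e-04, and C1orf116 by 0.75 ± 0.056, adjusted p = 1.77e-05. ZNF749, a zinc finger gene, was lower with MPA (-0.38 ± 0.053, adjusted p = 0.00617). FKBP5 differed by 0.31 ± 0.13 (95% interval 0.019 to 0.59, adjusted p = 0.551) and PER1 by 0.38 ± 0.10 (0.16 to 0.60, adjusted p = 0.234). ESR1 differed by -0.24 ± 0.065 (-0.38 to -0.10, adjusted p = 0.206) and PGR by -0.057 ± 0.056 (-0.18 to 0.064, adjusted p = 0.845), and none of these 4 was called. The glucocorticoid list was higher with MPA, 4 members called and 13 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.88e-11). So were the androgen list, 3 called and 5 higher and 0 lower when adjusted over the list alone (camera adjusted p = 5.45e-08), and the progestin list, 2 called and 7 higher and 0 lower when adjusted over the list alone (camera adjusted p = 3.71e-08). In all 43 probe sets were called, 35 higher and 8 lower with MPA, and 8 by at least 1.5-fold. Of 922 probe sets called with either compound against vehicle, 42 differed between them, and for 884 the 95% interval of the difference lay within 1.5-fold. That bound is wide. Of 910 probe sets called with MPA or DHT, 723 also lay within it, though 429 differed between those compounds. With MPA against vehicle only 168 of 880 calls reached 1.5-fold, so the 884 do not show equal responses to MPA and PROG. The higher THRSP (1.14 ± 0.19, adjusted p = 0.0187) lost its call without any 1 of MPA 2, MPA 3, PROG 1 and PROG 3 (adjusted p 0.0593 to 0.104). The lower AMIGO2 (-0.55 ± 0.10, adjusted p = 0.0383) lost it without any 1 of MPA 1, MPA 3, PROG 1, PROG 2 and PROG 3 (adjusted p 0.0957 to 0.147). The number of calls was 22 without MPA 3, 17 without PROG 1 and 19 without PROG 3. The 42 became 22 without MPA 3, 16 without PROG 1 and 17 without PROG 3. The 4 glucocorticoid-induced genes became 1 without MPA 3, PROG 1 or PROG 3, and the 2 progestin-induced genes 1 without MPA 1, MPA 3, PROG 1 or PROG 3.

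**Figure D3:**
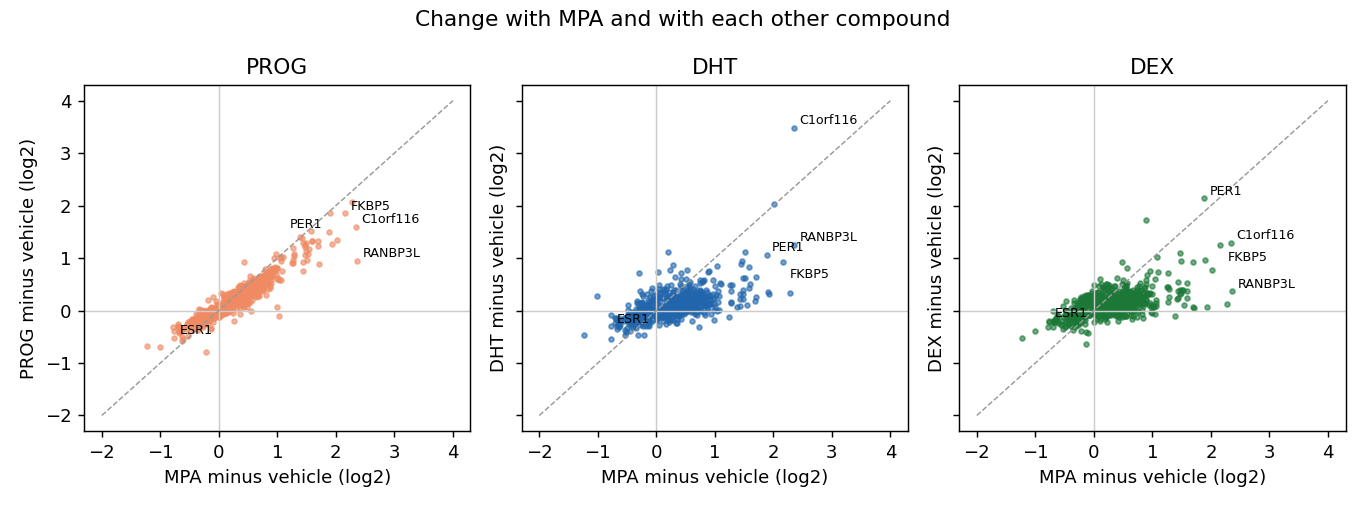
Each point is 1 of the 762 probe sets called by limma's F test, with its log2 change with MPA (horizontal axis) against its log2 change with PROG, DHT or DEX (vertical axis) and a dashed line of equal change. Across these probe sets, which were selected on these same changes, the median absolute change is 0.25 with PROG and 0.35 with MPA. C1orf116 lies above the line with DHT (3.48 against 2.35) and PER1 above it with DEX (2.14 against 1.88).

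MPA against DHT gave higher ZBTB7C (1.95 ± 0.12, adjusted p = 2.41e-07), SGPP2, a sphingosine-1-phosphate phosphatase (1.62 ± 0.11, adjusted p = 6.36e-07), EMP1 (1.55 ± 0.089) and FKBP5 (1.23 ± 0.13, adjusted p = 5.73e-05). HEY2 (-1.29 ± 0.089, adjusted p = 6.71e-07), C1orf116 (-1.13 ± 0.056, adjusted p = 4.07e-08), AMIGO2 (-0.76 ± 0.10), ESR1 (-0.47 ± 0.065, adjusted p = 5.00e-04) and PGR (-0.39 ± 0.056, adjusted p = 6.62e-04) were lower with MPA. OLR1, a receptor for oxidized LDL, was lower too (95% interval -1.17 to -0.83, adjusted p = 1.83e-06). It was the 1 probe set called in opposite directions against vehicle, 0.71 with DHT and -0.29 with MPA, values chosen for naming after they were seen. The calls numbered 521, 376 higher and 145 lower, and 99 were of at least 1.5-fold. Of the 610 probe sets raised by MPA, 331 were higher and 1 lower with MPA than with DHT, and of the 115 raised by DHT, 13 were higher and 47 lower with DHT than with MPA. Each set was chosen on the same treated arrays that enter its comparison, which favours higher values with the compound that defined it. Glucocorticoid-induced genes were higher with MPA in 21 of 29 cases and lower in 1, or 24 higher and 1 lower when adjusted over the list alone (camera adjusted p = 7.31e-32). Progestin-induced genes were higher in 15 of 27, or 18 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.70e-22), and metallothioneins in 2 of 8, or 4 higher and 0 lower when adjusted over the list alone (camera adjusted p = 2.36e-05). In the androgen list 5 were higher and 2 lower, or 9 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0478; adjusted p = 0.349 with an estimated correlation). That list's call ended without MPA 1 (adjusted p = 0.0681), MPA 3 (adjusted p = 0.0601), DHT 1 (adjusted p = 0.0519) or DHT 2 (adjusted p = 0.218). SERF2, a small basic protein, was lower with MPA (-0.71 ± 0.16, adjusted p = 0.0234), but it is 1 of the 16 probe sets highest in DHT 1 and DHT 2, with a DHT SD of 0.433. Its call ended without any 1 of MPA 1, MPA 2, DHT 1 and DHT 2 (adjusted p 0.0623 to 0.108). Leaving out 1 array took the 13 to 8 without vehicle 1, vehicle 2, MPA 1 or DHT 1, 7 without MPA 2 or DHT 2 and 37 without DHT 3, and the 47 to 30 without vehicle 2 and 27 without DHT 2. The 2 lower androgen-induced genes became 1 without MPA 1, DHT 1 or DHT 3.

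MPA against DEX gave higher ZBTB7C (2.17 ± 0.12, adjusted p = 7.61e-08), RANBP3L (2.00 ± 0.097, adjusted p = 2.66e-08, with a dim DEX mean of 3.89), SGPP2 (1.86 ± 0.11) and UNC5B (1.65 ± 0.080). FKBP5 (0.90 ± 0.13, adjusted p = 9.10e-04) was also higher with MPA. EPGN was lower with MPA by -0.83 ± 0.11, adjusted p = 2.82e-04, and so were ESR1 (-0.57 ± 0.065, adjusted p = 8.94e-05), PGR (-0.44 ± 0.056, adjusted p = 2.47e-04) and HEY2 (-0.62 ± 0.089). PER1 was not called (-0.26 ± 0.10, adjusted p = 0.246, 95% interval -0.48 to -0.032). The calls numbered 602, 369 higher and 233 lower, and 92 were of at least 1.5-fold. Of the 142 probe sets raised by DEX, 20 were higher and 58 lower with DEX than with MPA. The 142 were chosen on the same DEX arrays, which favours higher values with DEX. Glucocorticoid-induced genes were higher with MPA in 15 of 29 cases and lower in 2, or 18 higher and 4 lower when adjusted over the list alone (camera adjusted p = 1.68e-12). Androgen-induced genes were higher in 9 of 22, or 11 higher and 0 lower when adjusted over the list alone (camera adjusted p = 2.12e-10). Progestin-induced genes were higher in 13 of 27 and lower in 2, or 18 higher and 2 lower when adjusted over the list alone (camera adjusted p = 1.02e-15). Leaving out 1 array took the 20 to 12 without vehicle 1 or DEX 3 and 10 without vehicle 3, and the 58 to 38 without vehicle 2, 37 without vehicle 3, 33 without DEX 2 and 27 without DEX 3. The 2 lower progestin-induced genes became 0 without MPA 1, DEX 2 or DEX 3 and 1 without MPA 2 or MPA 3.

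PROG against DHT gave higher ZBTB7C (1.73 ± 0.12, adjusted p = 1.84e-06), EMP1 (1.49 ± 0.089), ACOT6 (1.33 ± 0.12), ACSL1 (1.07 ± 0.050) and FKBP5 (0.92 ± 0.13, adjusted p = 0.00144). C1orf116 (-1.89 ± 0.056, adjusted p = 1.64e-10), HEY2 (-0.97 ± 0.089), OLR1 (-0.96 ± 0.078) and PGR (-0.34 ± 0.056, adjusted p = 0.00469) were lower with PROG, and ESR1 was not called (-0.22 ± 0.065, adjusted p = 0.148). The calls numbered 254, 202 higher and 52 lower, and 50 were of at least 1.5-fold. Glucocorticoid-induced genes were higher with PROG in 16 of 29 cases, or 20 higher and 1 lower when adjusted over the list alone (camera adjusted p = 7.06e-28). For progestin-induced genes it was 13 of 27, or 16 higher and 0 lower when adjusted over the list alone (camera adjusted p = 2.03e-18). Androgen-induced genes had 3 higher and 3 lower with PROG, or 4 higher and 5 lower when adjusted over the list alone, without a camera call (adjusted p = 0.604). The number of calls was 168 without PROG 2 and 168 without DHT 1.

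PROG against DEX gave higher ZBTB7C (1.94 ± 0.12, adjusted p = 7.58e-07), ACOT6 (1.51 ± 0.12), SGPP2 (1.20 ± 0.11) and P3H2, a collagen prolyl hydroxylase (at least 1.16 ± 0.14, with a DEX mean of 3.40, under the array medians). EPGN (-0.99 ± 0.11, adjusted p = 1.50e-04), ANGPTL4 (-0.76 ± 0.082), PER1 (-0.64 ± 0.10, adjusted p = 0.00486) and PGR (-0.38 ± 0.056, adjusted p = 0.00194) were lower with PROG. The calls numbered 211, 153 higher and 58 lower, and 46 were of at least 1.5-fold. Of the glucocorticoid-induced genes 10 were higher and 5 lower with PROG, or 12 higher and 6 lower when adjusted over the list alone (camera adjusted p = 1.38e-05). Of the progestin-induced genes 9 were higher and 1 lower, or 11 higher and 3 lower when adjusted over the list alone (camera adjusted p = 6.13e-10). Androgen-induced genes were higher with PROG in 5 of 22 cases, or 8 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.19e-04; adjusted p = 0.0977 with an estimated correlation). The higher FKBP5 (0.60 ± 0.13, adjusted p = 0.0420) lost its call without any 1 of the 6 arrays (adjusted p 0.117 to 0.126). Its PROG arrays (6.09 to 6.12) all lay above its DEX arrays (5.50 to 5.51), and its error is pooled over all groups. The lower ESR1 (-0.33 ± 0.065, adjusted p = 0.0183) lost its call without any 1 of PROG 2, PROG 3 and DEX 2 (adjusted p 0.0673 to 0.0956). The 5 higher androgen-induced genes became 1 without PROG 1 or DEX 1 and 2 without PROG 2 or DEX 2. The 5 lower glucocorticoid-induced genes became 3 without PROG 1, PROG 2 or DEX 3 and 2 without DEX 1 or DEX 2, and the lower progestin-induced gene 0 without PROG 1, PROG 2, DEX 1, DEX 2 or DEX 3.

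DHT against DEX gave higher C1orf116 (2.18 ± 0.056, adjusted p = 2.23e-11), CLDN8 (1.25 ± 0.085, adjusted p = 6.19e-06), RANBP3L (0.89 ± 0.097, with a dim DEX mean of 3.89), OLR1 (0.76 ± 0.078) and AQP3 (0.72 ± 0.11). PER1 (-1.08 ± 0.10, adjusted p = 2.05e-04), EPGN (-0.98 ± 0.11, adjusted p = 3.42e-04), ANGPTL4 (-0.79 ± 0.082) and MYPN, a sarcomeric protein (-0.80 ± 0.10), were lower with DHT. ESR1 (-0.10 ± 0.065, 95% interval -0.24 to 0.036, adjusted p = 0.675) and FKBP5 (-0.32 ± 0.13, 95% interval -0.61 to -0.036, adjusted p = 0.449) were not called. For FKBP5 the DHT arrays (5.10 to 5.24) all lay under the DEX arrays (5.50 to 5.51). Its error is pooled over all groups, including the vehicle arrays, which spread from 3.83 to 4.48. The calls numbered 97, 38 higher and 59 lower, and 15 were of at least 1.5-fold. Glucocorticoid-induced genes were lower with DHT in 8 of 29 cases and higher in 1, or 2 higher and 14 lower when adjusted over the list alone (camera adjusted p = 1.91e-12). Androgen-induced genes were higher in 3 of 22, or 4 higher and 0 lower when adjusted over the list alone (camera adjusted p = 2.80e-04; adjusted p = 0.113 with an estimated correlation). Progestin-induced genes were lower in 3 of 27, or 1 higher and 8 lower when adjusted over the list alone (camera adjusted p = 0.00481; adjusted p = 0.0977 with an estimated correlation). Of the metallothioneins 1 was lower, or 0 higher and 2 lower when adjusted over the list alone (camera adjusted p = 1.36e-04). The number of calls was 62 without DHT 1 and 64 without DHT 2. The 15 of at least 1.5-fold became 35 without DHT 3, and the higher glucocorticoid-induced gene 0 without DHT 1, DHT 2, DEX 1 or DEX 3.

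**Figure D4:**
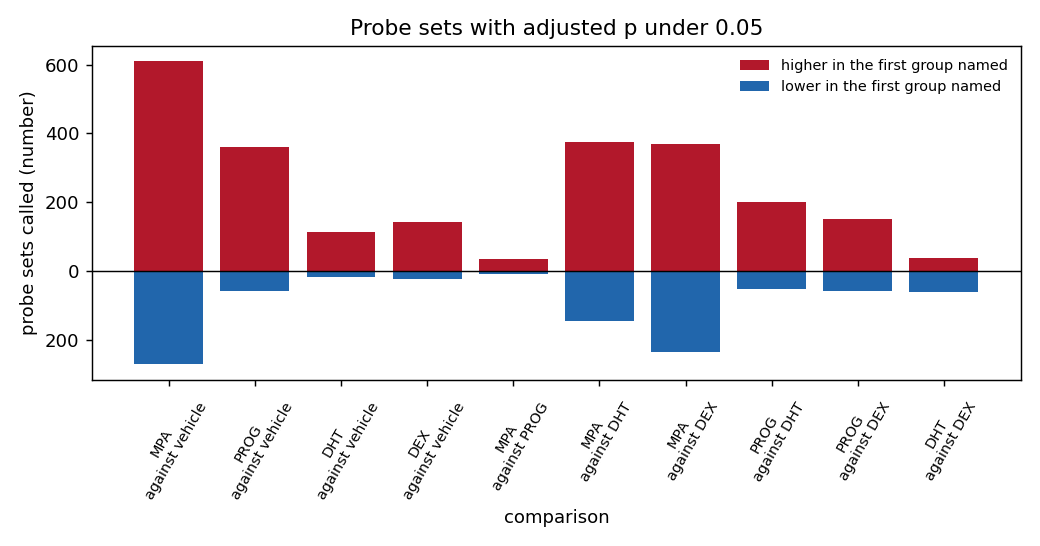
Bars give the number of probe sets (vertical axis, starting at 0) with a limma adjusted p under 0.05 in each of the 10 comparisons (horizontal axis), upward where higher and downward where lower in the group named first. The numbers run from 43 for MPA against PROG to 880 for MPA against vehicle.

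The responses were then set side by side. With all 4 compounds 52 probe sets rose, against 0.0011 for independent lists, among them C1orf116, PER1, FKBP5, KLF9 and HSD11B2. The 5 that were lower with all 4 were AMIGO2, BCL2, KLHDC10, NRCAM and SYT1, of which KLHDC10 was chosen for naming after its values were seen. With DHT, the call of AMIGO2 ended without any 1 of the 6 arrays (adjusted p 0.0713 to 0.176), that of NRCAM without any 1 of vehicle 2, vehicle 3 and DHT 2 (adjusted p 0.0541 to 0.0752) and that of SYT1 without any 1 of vehicle 3 and DHT 2 (adjusted p 0.0595 to 0.0709). With DEX, NRCAM lost its call without any 1 of the 6 arrays (adjusted p 0.0665 to 0.143), and SYT1 without any 1 of vehicle 1, vehicle 3, DEX 2 and DEX 3 (adjusted p 0.0563 to 0.107). MPA and PROG shared 330 raised and 47 lowered probe sets, where independent lists give 14.8 and 1.06. MPA shared 86 raised and 15 lowered with DHT (independent lists 4.73 and 0.309) and 109 raised and 15 lowered with DEX (5.84 and 0.40). PROG shared 76 raised and 10 lowered with DHT (2.80 and 0.0664) and 92 raised and 9 lowered with DEX (3.45 and 0.0860), and DHT and DEX shared 56 and 6 (1.10 and 0.0252). In 100 simulations of unchanged groups, with 3 vehicle arrays drawn anew and shared by all groups, at most 1 call was shared. No simulated probe set changed, so few calls could arise to be shared. This low number therefore does not show how much shared controls add to the shared calls. Across genes, which are not independent replicates, changes correlated with r = 0.807 ± 0.07 for MPA and PROG (± the jackknife standard error over arrays), 0.562 ± 0.093 for MPA and DHT, and 0.559 ± 0.091 for MPA and DEX. The values were 0.567 ± 0.11 for PROG and DHT, 0.586 ± 0.11 for PROG and DEX and 0.551 ± 0.14 for DHT and DEX. The simulations gave mean values of at most 0.502 and a highest value of 0.528, which the observed values of all pairs exceed. Simulated noise was independent between genes, so this range may be narrower than that of real arrays. The 5 pairs other than MPA and PROG lie within 1 jackknife standard error of the simulated mean. In every pair, however, r rose without any vehicle array and fell without any treated array. For MPA and DHT it was 0.598 without vehicle 1 and 0.544 without DHT 1. The jackknife error includes this shift, so it cannot decide whether these 5 pairs differ from no response. The covariance exceeded the simulated one by 0.0144 for MPA and PROG, 0.00740 for MPA and DHT, 0.00694 for MPA and DEX, 0.00533 for PROG and DHT, 0.00529 for PROG and DEX and 0.00368 for DHT and DEX, without an error computed for it. The 3 vehicle arrays cannot be split, so part of the excess in shared calls may come from the shared controls. A solvent effect common to the treated groups, which the labels leave open, could also add to the shared calls. This holds for the 52 raised with all 4 compounds as well.

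Leaving out 1 array moved several of these shared numbers. The 62 calls that DHT and DEX shared, PER1 and C1orf116 among them, became 36 without vehicle 1, 33 without vehicle 2, 38 without vehicle 3, 38 without DHT 1, 31 without DHT 2, 33 without DEX 2 and 33 without DEX 3. The 124 of MPA and DEX became 73 without vehicle 1, 80 without vehicle 2, 77 without vehicle 3, 70 without DEX 2 and 59 without DEX 3. The 101 of MPA and DHT became 61 without vehicle 2, 65 without DHT 1 and 53 without DHT 2, and the 377 of MPA and PROG became 244 without PROG 2. The 101 of PROG and DEX became 61 without vehicle 1, 58 without vehicle 2, 62 without vehicle 3, 55 without DEX 2 and 49 without DEX 3. The 86 of PROG and DHT became 56 without vehicle 2 and 47 without DHT 2. The 52 raised with all 4 compounds became 34 without vehicle 1 or vehicle 3, 27 without vehicle 2, 33 without DHT 1, 30 without DHT 2, 31 without DEX 2 and 29 without DEX 3, and the 5 lowered 0 without vehicle 1 or DHT 2, 3 without vehicle 2, MPA 1 or MPA 3, 2 without vehicle 3, PROG 1, PROG 2, PROG 3 or DEX 1 and 1 without DEX 2 or DEX 3.

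Over all 5 groups, limma's F test called 762 probe sets of 760 genes. Among these the median absolute log2 change was 0.35 with MPA, 0.25 with PROG, 0.13 with DHT and 0.14 with DEX. The set was selected on these same changes, and MPA had the most calls against vehicle. The medians are therefore no independent ranking of the compounds.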

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

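No test in this part was chosen after its result was seen. The 20037 probe sets without a gene name here enter none of the comparisons above, and some of them differed from vehicle in a limma fit over all probe sets of the table at an adjusted p under 0.05. With MPA 567 unnamed probe sets differed from vehicle, 392 higher and 175 lower, beside 737 named ones in the same fit. With PROG 252 differed, 210 higher and 42 lower, beside 336 named ones. With DHT 58 differed, 51 higher and 7 lower, beside 83 named ones, and with DEX 89 differed, 77 higher and 12 lower, beside 117 named ones. The largest rise among the unnamed probe sets was 2.74 on the log2 scale with MPA, 2.40 with PROG, 1.54 with DHT and 1.94 with DEX. The largest fall was -1.14 with MPA, -0.60 with PROG, -1.24 with DHT and -0.57 with DEX, and no biological explanation was tested for them.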

How the results depend on the processing

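No test in this part was chosen after its result was seen. No named gene called in the main fit or in an alternative, and no list called in the main fit, changed direction. The direction of other genes and lists was not followed. In the order MPA, PROG, DHT and DEX against vehicle, then MPA against PROG, MPA against DHT, MPA against DEX, PROG against DHT, PROG against DEX and DHT against DEX, fits of only the 2 groups compared called 526, 255, 54, 44, 7, 292, 285, 146, 122 and 39 probe sets, with fewer arrays to estimate the spread, and a minimum of 1.5-fold kept 168, 85, 25, 21, 8, 99, 92, 50, 46 and 15. The filter on dim probe sets gave 211 calls for DHT against vehicle and 153 for DHT against DEX, and trend and robust settings gave 222, 166 and, for MPA against PROG, 72; the cause was not tested. Among probe sets called by the F test, the changes with MPA and PROG correlated with r = 0.941, in sets selected for change that share the vehicle arrays, and no value without response was simulated for them. With 1 array left out, the comparisons in the same order gave 674 to 855, 257 to 336, 66 to 132, 78 to 123, 17 to 38, 380 to 459, 422 to 539, 168 to 256, 144 to 169, 62 to 135 calls and the F test 644 to 752. Shared calls then ranged over 244 to 366 for MPA and PROG, 53 to 101 for MPA and DHT, 59 to 119 for MPA and DEX, 47 to 72 for PROG and DHT, 49 to 87 for PROG and DEX, 31 to 44 for DHT and DEX, and correlations over 0.77 to 0.821 for MPA and PROG, 0.505 to 0.6 for MPA and DHT, 0.519 to 0.597 for MPA and DEX, 0.499 to 0.626 for PROG and DHT, 0.541 to 0.643 for PROG and DEX, 0.476 to 0.612 for DHT and DEX. Of 247 calls of named genes, 68 were lost with only the 2 groups fitted, 28 with all probe sets tested, 26 without moderation, 14 after quantile normalization and 10 after median centring, and 59 with at least 1 array left out. Camera lost 36 of 77 list calls with an estimated correlation, and fry lost 2.

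The replicate numbers do not pair the arrays: over 30 same-numbered pairs the residuals correlated with r from -0.072 to 0.068, 0 pairs were above 0.1, and 0 arrays correlated best with their own number in all 4 other groups. With the replicate number as a block the comparisons in the same order gave 829, 381, 100, 147, 36, 479, 530, 234, 194 and 71 calls and the F test 676, 20 of 247 calls of named genes and 2 of 77 list calls were lost, and it changed the call of no other named gene or list. Array signal limits the dim genes: 40% of the named probe sets lie under a mean of log2 3.9, close to the array medians, where a change is hard to measure.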

Other observations

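The tests on the probe sets highest in DHT 1 and DHT 2 were chosen only after that result was seen, and the other tests in this part were written before their results were seen. In further lists, 6 of 29 G1-S and DNA replication genes rose with MPA, or 8 higher and 0 lower when adjusted over the list alone, among them CCNE2, a cyclin of S phase entry (0.41 ± 0.055). With PROG 4 rose, or 6 higher and 0 lower when adjusted over the list alone, with CCNE2 at 0.43 ± 0.055. Camera placed the list higher with MPA (adjusted p = 0.00101; adjusted p = 0.234 with an estimated correlation) and with PROG (adjusted p = 9.70e-05; adjusted p = 0.145 with an estimated correlation). It made no call with DHT (adjusted p = 0.931) or DEX (adjusted p = 0.0858). Leaving out 1 array took the 6 with MPA to 2 without vehicle 1 or MPA 3, and the 4 with PROG to 1 without vehicle 1 or PROG 2 and 2 without vehicle 2, PROG 1 or PROG 3. Of 6 sodium and water transport genes, 3 were called higher with MPA, 3 with PROG, 2 with DHT and 1 with DEX. AQP3 and HSD11B2 rose with MPA, PROG and DHT, AQP3 by 1.51 ± 0.11, 0.96 ± 0.11 and 1.11 ± 0.11, and HSD11B2 rose with DEX. HSD11B2 and SGK1 are also members of the progestin-induced list, so AQP3 is the only called member not counted there. The third call with MPA and PROG is SGK1, which lies under the array medians and lost its MPA call without any 1 of vehicle 1, MPA 2 and MPA 3 (adjusted p 0.0568 to 0.0939). Camera placed the list higher with all 4 (with MPA adjusted p = 5.33e-05; with PROG adjusted p = 5.89e-06; with DHT adjusted p = 8.03e-04; with DEX adjusted p = 4.96e-04). Adjusted over the list alone, 4, 4, 2 and 3 of these genes rose with MPA, PROG, DHT and DEX. Of 12 circadian clock genes, PER1 and CRY2, both transcriptional repressors of the clock, were called higher with all 4 compounds, CRY2 by 0.51 ± 0.041 with MPA, 0.35 ± 0.041 with PROG, 0.20 ± 0.041 with DHT and 0.41 ± 0.041 with DEX. The CRY2 call with DHT ended without any 1 of vehicle 1, vehicle 2, vehicle 3, DHT 1 and DHT 2 (adjusted p 0.0541 to 0.146). PER2 was also called higher with MPA and DEX, calls that ended without any 1 of vehicle 1, MPA 1 and MPA 3 (adjusted p 0.0516 to 0.0623) and without any 1 of the 6 arrays (adjusted p 0.0875 to 0.165), and NPAS2 lower with MPA, a call that ended without any 1 of vehicle 1, vehicle 3 and MPA 2 (adjusted p 0.0651 to 0.0803). The members called were thus 3 higher and 1 lower with MPA, 2 higher with PROG, 2 with DHT and 3 with DEX, or, when adjusted over the list alone, 3 higher and 3 lower, 3 higher, 2 higher and 3 higher. Camera called the list with DEX (adjusted p = 0.00917; adjusted p = 0.104 with an estimated correlation) and not with MPA (adjusted p = 0.677), PROG (adjusted p = 0.239) or DHT (adjusted p = 0.204).

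Luminal epithelial markers had a camera call with DEX (adjusted p = 0.00787; adjusted p = 0.249 with an estimated correlation), which ended without DEX 2 (adjusted p = 0.0841). With MPA it had none (adjusted p = 0.205), though 4 of 16 were higher, such as the keratin KRT19 (0.37 ± 0.045), and 2 lower, or 4 higher and 2 lower when adjusted over the list alone. Heat shock genes were higher with DHT in camera (adjusted p = 0.00159; adjusted p = 0.0817 with an estimated correlation), with 1 of 7 called over all genes (0 without DHT 2), or 1 higher and 0 lower when adjusted over the list alone. Interferon-induced genes were lower with DHT in camera (adjusted p = 0.0292; adjusted p = 0.0817 with an estimated correlation) with 0 of 14 members called over all genes, or 0 higher and 0 lower when adjusted over the list alone. That call ended without vehicle 1 (adjusted p = 0.0577), vehicle 2 (adjusted p = 0.0523) or DHT 3 (adjusted p = 0.117). Camera made no call against vehicle for 14 lists, whose lowest adjusted p was 0.0588. This covers only their measured members. Measured were 6 of 25 steroid metabolism enzymes, 5 of 14 fibroblast markers, 8 of 19 basal markers and 7 of 17 housekeeping genes, for example. The 14 lists are the estrogen-induced genes, androgen-regulated secreted proteins, steroid metabolism enzymes, NF-kB inflammatory genes, sterol synthesis genes, mitotic genes, unfolded protein response genes, hypoxia genes, polyamine enzymes, basal, fibroblast and blood or endothelial markers, ribosomal protein genes and housekeeping genes. Single members were called in some of these lists, such as EGFR, a basal marker that encodes a growth factor receptor (0.77 ± 0.049 with MPA), and the hypoxia gene NDRG1 (1.48 ± 0.17 with MPA).

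Genes higher with DHT than with DEX, such as C1orf116 and CLDN8, had a median MPA minus PROG difference of 0.10 over 36 such genes, of which 26 were positive. A larger MPA response in general and a shared component of the MPA and DHT responses cannot be told apart here: 0.033 of 10000 draws of genes matched on mean change had a median as high (1-sided), under the bound of 0.05 set before, but the observed 0.103 lies inside the 95% range of the draws, 0.0083 to 0.11. The 59 genes lower with DHT than with DEX had a median difference of 0.043 with 43 positive, a like share, and 0.806 of matched draws were as high. The range was required only after these values were seen, and by the first bound alone a larger MPA response was argued against. Binding of the compounds was not measured.

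In 16 probe sets of 14 genes, including ABHD11, FDPS, RNF185, EAF1 and SERF2, DHT 1 and DHT 2 exceeded all other arrays by over 0.3, against at most 2 probe sets for any other pair within a group. A weaker response of DHT 3 is argued against for the androgen-induced list, whose mean change there was 118% of that in DHT 1 and DHT 2. On principal component 2 of the named probe sets, DHT 3 lay at 3.01, and DHT 1 and DHT 2 at 9.93 and 10.1. A difference of DHT 3 beyond that list therefore stays open. A change in the whole RNA is argued against for the 12 genes with another probe set outside the set, since these other probe sets differed by 2.64% as much (0.019 against 0.72). Probe sets inside the set did not count as others, which for F8A1 leaves out further ones that showed the pattern. The 0.72 comes from probe sets chosen for this difference. An array-to-array factor that also varies in the other groups may be the source, because the set's deviations correlated over the 12 other arrays with a mean r of 0.239, which 0.002 of 1000 random sets reached, and 0.001 of sets drawn among genes with several probe sets. That test was first run on the 4 genes whose brightest probe set is in the set where it gives a mean r of -0.044 with a share of 0.618, the opposite reading, and it was redone on all 14 genes, and the test of the other probe sets added, after that result was seen. Of these genes 12 of 14 have several probe sets (85.7%, against 2.82% of all genes), no biological explanation was tested, and what the factor is stays open.

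ESR1 fell with MPA and PROG together with RMND1 (-0.66 ± 0.059 and -0.41 ± 0.059) and CCDC170 (-0.62 ± 0.065 and -0.55 ± 0.065), its nearest measured neighbours on 1 side. Neighbours and adjacent pairs here are taken among measured protein-coding genes only. Genes without a named probe set may lie between them and were not tested. ZBTB2 next to them was not called with MPA (-0.16, adjusted p = 0.106). Nor were MYCT1, VIP, FBXO5 and MTRF1L, the nearest measured genes on the other side (0.080, -0.077, 0.093 and 0.070, adjusted p 0.223 to 0.619). Of these, MYCT1 and VIP lie under the array medians. Placement of lowered genes at random over the measured protein-coding genes was argued against. With MPA 15 adjacent pairs were both lower, where 10000 permutations of the calls gave a mean of 5.35 (permutation p = 3e-04). Neighbours that overlap on the genome do not account for it, as 13 pairs stayed against 4.97 with overlapping pairs left out (permutation p = 0.0011), and 11 against 4.95 without pairs of RMND1, CCDC170 or ESR1 as well (permutation p = 0.0101). Raised genes also lay next to each other with MPA, 54 pairs against 26.8 (p = 1e-04, the smallest that these permutations can give), and with PROG, 20 against 10.3 (permutation p = 0.0036), and 4 lowered pairs with PROG stood against 0.204 (p = 1e-04, likewise the smallest; 2 against 0.181, permutation p = 0.0158, without overlapping pairs and those of RMND1, CCDC170 or ESR1), while raised pairs numbered 1 against 0.850 with DHT (permutation p = 0.576) and 3 against 1.47 with DEX (permutation p = 0.177), and the 16 lowered genes with DHT and 19 with DEX are too few for this test. The permutations did not match genes on level, and dim genes are hard to call. These excesses therefore cannot separate shared regulation from neighbours of like level. Regulation of a neighbourhood may be involved but was not tested, and neither were probe sequences shared between neighbours.

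For each comparison, 1 of the 10 splits of its 6 arrays into 3 and 3 gave as many calls, the real one, and 10 splits are too few for a share under 0.05. The real number and the highest of the other splits were 880 and 1 for MPA against vehicle, 419 and 0 for PROG, 132 and 1 for DHT, 164 and 1 for DEX, 43 and 1 for MPA against PROG, 521 and 0 for MPA against DHT, 602 and 1 for MPA against DEX, 254 and 1 for PROG against DHT, 211 and 0 for PROG against DEX, and 97 and 1 for DHT against DEX. For the F test 1 of 100 splits of the 15 arrays gave as many calls, the real one. The real split called 762 probe sets against at most 2 in the others. If the arrays vary independently, chance as the whole source of the group differences is excluded at that share. The labels do not say that the arrays came from separate cultures. Chance differences between cultures shared by the arrays of a group would not be excluded by this test.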
